A study of Homo sapiens with 6 samples.

How the data were processed

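Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out for 2 transcription factors in 2 human bronchial epithelial cell lines. Calu-3 was derived from a lung adenocarcinoma, and 16HBE14o- is an immortalised bronchial epithelial line. The 6 samples formed 3 groups of 2 samples each, namely KLF5 in Calu-3, KLF5 in 16HBE14o- and CEBPB in Calu-3. Per the labels' protocols, the cells were untreated and the nuclear lysate was sonicated before precipitation. Both 16HBE14o- KLF5 samples and 1 of the 2 Calu-3 KLF5 samples were precipitated with the same commercial antibody, whereas the other Calu-3 KLF5 sample was precipitated with a rabbit antibody. Cell line and antibody were therefore partly confounded in every comparison of the 2 KLF5 lists.

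The deposited data consisted of 1 peak list per group. Per the series' design text, each list was made from both samples of its group, so no list of a single sample was analysed here. Agreement between samples entered only through the authors' own filtering and could not be checked further. Whether the 2 samples of a group came from separate cultures was not stated in the labels. Coordinates were on hg19, per the file headers and the submitters' processing notes. The KLF5 lists were named as optimal peaks of the irreproducible discovery rate (IDR) procedure, per the file headers, and the CEBPB list as IDR peaks. The aligner, the peak caller, the filters and the control library were not given in the sources used here.

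Each deposited peak carried a signal value and a score set by the authors, whose normalization was not stated. These were used to rank, filter or describe peaks within 1 list. Signals were set against each other between lists only as correlations across overlapping pairs of peaks. Ranks are given as percentiles of the authors' signal, with 100 for the highest peak of a list. Deposited scores of the KLF5 lists ran from 540 to 1000. On the scale that IDR programs use, the negative of 125 times the base 2 logarithm, the minimum corresponds to an IDR of 0.0501, an inference from the values and not a statement of the submitters. Deposited CEBPB scores were the whole part of 10 times the −log10 of the p-value and were not IDR values. The authors' −log10 q-values were used as a filter and for an alternative ranking. Sequencing depth is unknown because the lists hold no read counts.

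Peaks were called overlapping when they shared at least 1 bp, and overlapping entries of the same list were kept as separate peaks. The chance level of an overlap came from 10000 circular shifts of 1 list along its chromosomes, within the span from the first to the last base covered by any list, with a one-sided p whose smallest possible value was 0.0001. Such shifts ignore open chromatin and mappability, so any pair of lists of active regions can exceed them. Stricter levels were therefore computed as well, from local shifts of 5 to 50 kb and from random draws of CEBPB peaks, with 1000 repeats each. Shares are given with exact (Clopper-Pearson) 95% confidence intervals and differences with Newcombe intervals. All intervals cover counting error only. Shares were compared with two-sided Fisher's exact tests and medians of signal percentiles with two-sided permutation tests of 100000 resamples, whose smallest possible p was 1e-05. Benjamini-Hochberg adjustment was applied within each family, and the threshold was 0.05. Peaks are not replicates, so every p-value compares these lists and not the cell lines, the factors or the antibodies.

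The overlap tests, the comparison of CEBPB shares, the comparison of signal ranks and the rule for named regions were fixed before the data were examined. Under that rule the text names the 5 peaks of highest signal in each list and in each overlap class, the rank of an overlap being the mean of both percentiles. The comparisons of chromosomes and of 5 Mb bins, the bounds of the regions on chromosomes 3 and 20, the comparison of the 10% of CEBPB peaks with the highest signal, the local shifts, the filter on CEBPB q-values, the restriction to KLF5 peaks of the highest score, the exclusion of chromosomes 3 and 20, the relation across bins with and without these parts, the CEBPB overlap within the regions of chromosome 3 and the stratified test were chosen after the data had been seen. Further alternatives varied the overlap rule, the signal threshold, the list sizes, the peak width, the chromosomes used and the merging of entries.

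Analyses of promoters, binding motifs and gene lists had been planned but were not run, because neither an hg19 gene annotation nor the hg19 sequence was used here and coordinates were not converted between assemblies. Regions are therefore given by hg19 position alone, with no genes assigned. The scripts were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. The overlap test was tested on simulated data with lists of the observed sizes. Simulated peaks had the same width within a list and were placed independently and evenly, unlike the grouped peaks of the real lists. The simulations therefore do not show how the test behaves on grouped peaks or on lists of active regions. For the 2 KLF5 lists, and likewise for KLF5 and CEBPB in Calu-3, 0 of 20 simulations without planted overlaps and 20 of 20 with 20 planted overlaps fell below the threshold. The test of shares fell below the threshold in 8 of 200 simulations with equal shares and in 200 of 200 with shares of 0.4 and 0.3. These shares were drawn as independent peaks, which the real peaks need not be.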

Results

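The binding of KLF5, a Krüppel-like zinc finger transcription factor, was profiled by ChIP-seq in the bronchial epithelial lines Calu-3 and 16HBE14o-, and the binding of CEBPB, a basic leucine zipper transcription factor, was profiled in Calu-3. Calu-3 KLF5 gave 1510 peaks with a median width of 280 bp, and 16HBE14o- KLF5 gave 3262 peaks with a median width of 344 bp. The Calu-3 CEBPB list was far longer, with 69386 peaks of 151 bp median width that covered 11914 kb, against 419 kb and 1086 kb for the KLF5 lists. It also held a smaller share of peaks with low q-values. Only 46.3% of its peaks had a q-value of 0.05 or less, compared with 86.6% of the Calu-3 and 78.9% of the 16HBE14o- KLF5 peaks. Its lowest −log10 q-value, 0.0946, was nonetheless above those of the Calu-3 (0.0324) and 16HBE14o- (0.0124) KLF5 lists. The peak caller was not given, so q-values need not be comparable between the CEBPB and KLF5 lists. Each list was made from both samples of a group, so the values below carry no measure of error between samples.

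The first comparison asked how far KLF5 occupied the same sites in both lines. Most KLF5 peaks were listed in 1 line only, which at unknown depth does not show that the other line lacked binding. Of the Calu-3 peaks, 356 of 1510 overlapped a 16HBE14o- KLF5 peak (23.6%, 95% confidence interval 21.5 to 25.8), leaving 1154 Calu-3-only peaks. In the other direction, 368 of 3262 16HBE14o- peaks overlapped a Calu-3 peak (11.3%, 10.2 to 12.4), leaving 2894 peaks seen in 16HBE14o- only. The shared sites were nonetheless far more numerous than chance placed together. Circular shifts gave a mean of 1.35 overlapping Calu-3 peaks and a maximum of 15 (permutation p = 0.0001, the smallest that 10000 shifts can give). Local shifts gave a mean of 6.01, and CEBPB peaks drawn at random in place of the Calu-3 KLF5 list gave 15.4. With both lists limited to their 1510 peaks of highest signal, 17.9% of the 16HBE14o- peaks were shared.

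The strongest shared site lay on chromosome 5 at positions 138088859 to 138089128, the highest peak of the 16HBE14o- list (signal 201) and at percentile 99.5 of the Calu-3 list. Next came a site on chromosome 19 at 50718442 to 50718721, at percentile 99.4 in Calu-3 and 99.97 in 16HBE14o-. The other 3 of the 5 highest shared sites were on chromosome 20 at 60936996 to 60937126 and at 30160678 to 30160957, and on chromosome 12 at 125117887 to 125118166. All 5 of the highest 16HBE14o- peaks had a Calu-3 KLF5 peak, including those on chromosome 20 at 49407291 to 49407524 and 30102075 to 30102264 and on chromosome 5 at 37272787 to 37272984.

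Among the 5 highest Calu-3 peaks, 3 were shared and 2 were not. The highest, on chromosome 3 at 193852569 to 193852984 (signal 240), had no 16HBE14o- peak over it, whereas the third, at 193853697 to 193853880 on the same chromosome, overlapped a 16HBE14o- peak of percentile 30.2. The second, on chromosome 7 at 2563873 to 2564091 (signal 178), was overlapped by neither 16HBE14o- KLF5 nor Calu-3 CEBPB. A shared peak on chromosome 8 at 145014509 to 145014606 and another on chromosome 20 at 30292420 to 30292699 completed the 5. Further Calu-3-only peaks of high signal lay on chromosome 3 at 193720896 to 193721175 and 193721528 to 193721597 and on chromosome 8 at 21988720 to 21988999. The highest peaks found only in 16HBE14o- were on chromosome 14 at 55570088 to 55570223 (signal 149), on chromosome 20 at 52364830 to 52364920 and 61002517 to 61002860, and on chromosome 17 at 41150123 to 41150466 and 41400778 to 41401121.

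Shared KLF5 sites ranked higher in both lists. In Calu-3 the median signal percentile was 68.8 for shared and 45.9 for Calu-3-only peaks, and in 16HBE14o- it was 74.2 for shared and 46.8 for the remaining peaks (permutation p = 1e-05 in each list, the smallest possible). The share of Calu-3 peaks also found in 16HBE14o- was 14.9% in the lowest 25% by signal and 40.7% (35.7 to 45.9) in the highest 25%. For 16HBE14o- peaks it was 5.28% and 22.1% (19.3 to 25.1). The 375 overlapping pairs of KLF5 peaks had a median distance of 35 bp between summits. Across these pairs the signals of both lists were weakly related (Spearman rho = 0.21, adjusted p = 6.0e-05; Pearson r = 0.21 on the log2 scale, permutation p = 7.0e-05), peaks not being independent replicates.

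Within Calu-3, the comparison of KLF5 with CEBPB asked how often both factors were called at the same site. CEBPB peaks overlapped 660 of the 1510 KLF5 peaks (43.7%, 41.2 to 46.3), whereas circular shifts gave a mean of 18.3 peaks and a maximum of 48 (permutation p = 0.0001, the smallest possible). Local shifts gave a mean of 26.6 peaks and a maximum of 44. Neither kind of shift accounts for open chromatin that both factors may share. Seen from CEBPB, 651 of 69386 peaks (0.938%, 0.868 to 1.01) had a KLF5 peak. The 662 overlapping pairs had a median summit distance of 30 bp and a Spearman rho of 0.15 between signals (adjusted p = 0.00018). These shares depended on the length of the CEBPB list, and with all lists limited to 1510 peaks 17.4% of KLF5 and 17.3% of CEBPB peaks overlapped. The share of CEBPB peaks with KLF5 was 1.80% for CEBPB peaks with a q-value of 0.05 or less and 0.450% when only KLF5 peaks of the highest score were used.

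**Figure D1:**
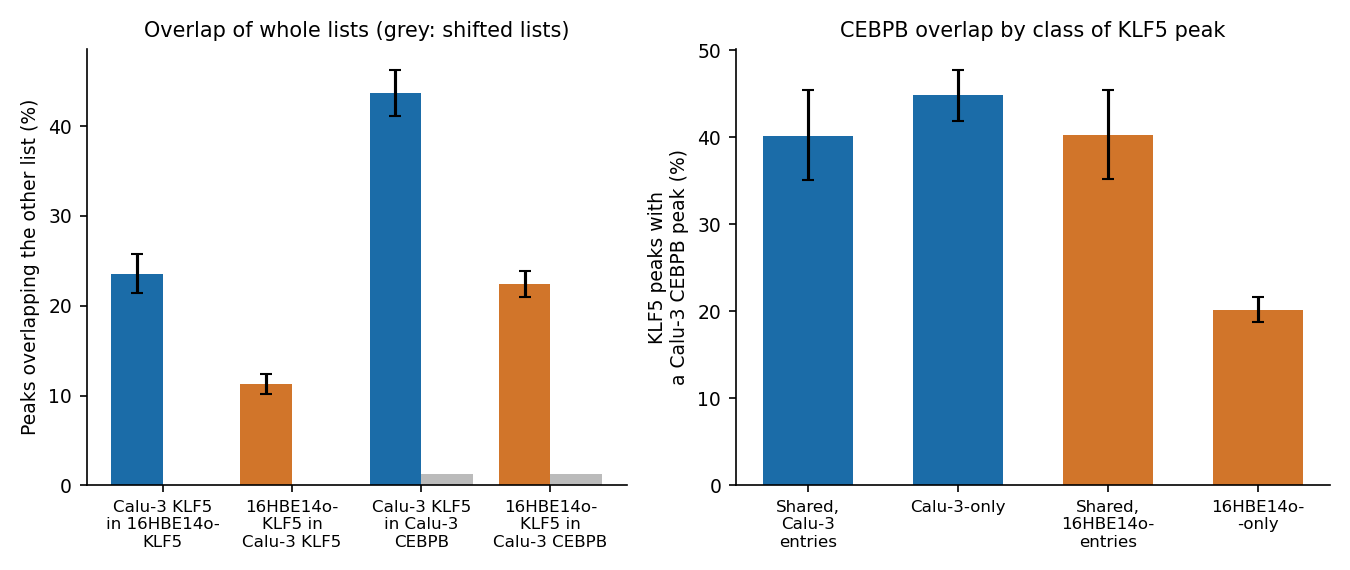
Percent of peaks in each list that overlapped another list, beside the mean of circular shifts (left), and percent of KLF5 peaks with a Calu-3 CEBPB peak in each overlap class (right), with exact 95% confidence intervals as error bars. The chance bars of the KLF5 lists, at 0.0891% and 0.0432%, are too low to be seen, and the class found only in 16HBE14o- stands lowest in the right panel at 20.2%.

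The highest-ranked sites of both factors lay on chromosome 1 at 31584116 to 31584395, where the CEBPB peak was at percentile 99.99, and on chromosome 14 at 35872942 to 35873221, which was also in the 16HBE14o- KLF5 list. The others of the 5 were on chromosome 20 at 23342470 to 23342749, chromosome 8 at 126442312 to 126442591 (also in the 16HBE14o- list, at percentile 16.0) and chromosome 12 at 25539131 to 25539410. Several of the strongest Calu-3 KLF5 sites had no CEBPB peak, among them the sites on chromosomes 7, 3, 8 and 20 already named at 2563873, 193853697, 145014509 and 30292420, and a site on chromosome 7 at 577958 to 578093. Of the 5 highest CEBPB peaks, only the one on chromosome 2 at 12596420 to 12596940 had a KLF5 peak, at percentile 85.3 of the Calu-3 list. The other 4, which no KLF5 list overlapped, were on chromosome 4 at 154582359 to 154583062 (signal 61.3), chromosome 15 at 68132306 to 68132715, chromosome 12 at 129423427 to 129423795 and chromosome 1 at 36952522 to 36952860.

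KLF5 peaks with a CEBPB peak had a median signal percentile of 52.7, against 48.0 for those without (difference 4.77 points, permutation p = 0.0623), which did not pass the threshold. The difference passed it under 5 of the 11 alternatives and had the opposite sign, at -1.92 points, in the 50% of peaks with the higher signal. All 3 lists met at 143 Calu-3 KLF5 peaks (9.47%). Another 517 had CEBPB only, 213 had 16HBE14o- KLF5 only, and 637 (42.2%) had neither. Sites in all 3 lists were ranked by their percentiles in the 2 KLF5 lists, without CEBPB. The 5 highest were those on chromosome 5 at 138088900 and on chromosome 20 at 60936996 and 30160678, with chromosome 20 at 36771739 to 36772018 and chromosome 22 at 46481638 to 46481917. Their CEBPB peaks were at percentiles 5.69, 83.2, 98.0, 99.2 and 86.7 in that order, so the first was weak for CEBPB.

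The third comparison asked whether CEBPB in Calu-3 lay more often at KLF5 sites of that line than at those of 16HBE14o-. Calu-3-only KLF5 peaks had a CEBPB peak in 517 of 1154 cases (44.8%, 41.9 to 47.7). KLF5 peaks found only in 16HBE14o- had a Calu-3 CEBPB peak in 584 of 2894 cases (20.2%, 18.7 to 21.7). The difference was 24.6 points (21.4 to 27.8; Fisher's exact test, adjusted p = 1.8e-53 over 3 tests). Shared sites were counted in the list of the class they were compared with. As 16HBE14o- peaks, 148 of 368 had CEBPB (40.2%, 35.2 to 45.4), which exceeded the share at sites found only in 16HBE14o- by 20.04 points (14.9 to 25.3, Fisher's exact test, adjusted p = 4.5e-16). As Calu-3 peaks, 143 of 356 had CEBPB (40.2%, 35.0 to 45.5), which differed from the Calu-3-only sites by -4.63 points (-10.4 to 1.27, Fisher's exact test, adjusted p = 0.127). The last difference passed the threshold under 6 of 10 alternatives. With all lists limited to 1510 peaks, the excess over the sites found only in 16HBE14o- was 7.61 points.

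Sites of 16HBE14o- KLF5 as a whole also overlapped Calu-3 CEBPB above chance, at 732 of 3262 peaks (22.4%, 21.0 to 23.9) against a mean of 41.0 in circular shifts (permutation p = 0.0001, the smallest possible). This share was 13.7% when summits within 100 bp were required and 2.98% with all lists limited to 1510 peaks.

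The CEBPB peaks at KLF5 sites also differed in strength. Among the 10% of CEBPB peaks with the highest signal, 6.14% (5.58 to 6.73) had a Calu-3 KLF5 peak, compared with 0.360% (0.315 to 0.410) of the rest. CEBPB peaks at Calu-3-only KLF5 sites belonged to that top class in 364 of 511 cases (71.2%, 67.1 to 75.1). At KLF5 sites found only in 16HBE14o- this held for 117 of 567 (20.6%, 17.4 to 24.2), and at shared sites for 62 of 140 (44.3%, 35.9 to 52.9). The difference between the first and the second was 50.6 points (45.2 to 55.5; Fisher's exact test, p = 4.8e-65). With all lists limited to 1510 peaks, the top class held only 151 CEBPB peaks, and 21.2% of 236 peaks at Calu-3-only sites stood against 0 of 20 at sites found only in 16HBE14o-, too few to size the difference. The excess of 5.78 points in the top class over the rest ranged from 2.94, with KLF5 peaks of the highest score, to 21.3, with lists of 1510 peaks. The highest score left only 695 Calu-3 KLF5 peaks, which lowered both shares, to 3.10% in the top class and 0.155% in the rest.

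**Figure D2:**
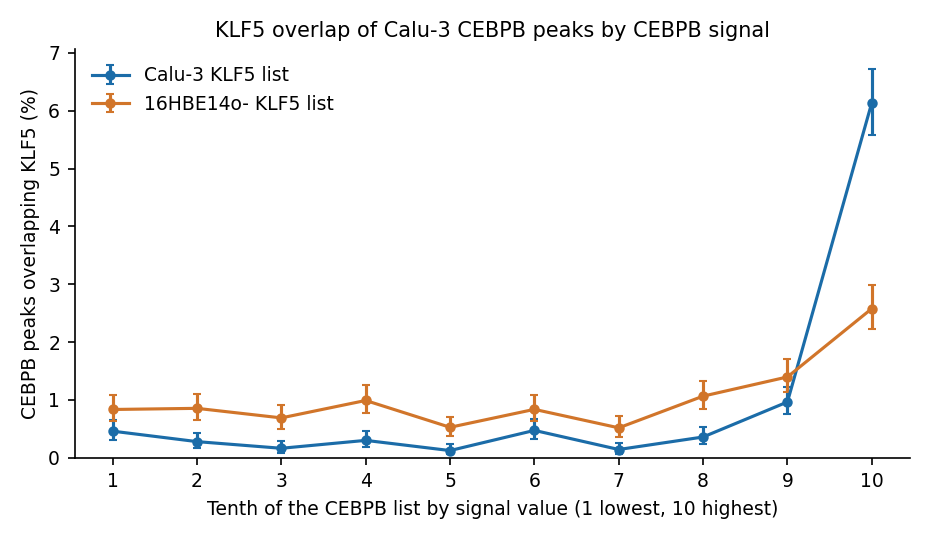
Percent of Calu-3 CEBPB peaks with a KLF5 peak, in 10 classes of about equal size by the authors' signal, with exact 95% confidence intervals as error bars. The class of highest signal stands apart for the Calu-3 KLF5 peaks, at 6.14%, and less so for the 16HBE14o- KLF5 peaks, at 2.58%.

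KLF5 peaks of both lines were spread differently over the chromosomes. Of 24 chromosomes, 6 held a higher share of the Calu-3 list (chromosomes 3, 5, 7, 8, 10 and 19) and 8 a higher share of the 16HBE14o- list (chromosomes 6, 11, 14, 16, 17, 20, 21 and X) after adjustment over all 24. Shares within a list have a fixed total, so a large excess on chromosome 3 lowers the Calu-3 shares of the other chromosomes. The tests are therefore not independent, and the smaller differences were not retested without chromosome 3. Chromosome 3 held 243 of the 1510 Calu-3 KLF5 peaks (16.1%) and 113 of the 3262 16HBE14o- peaks (3.46%, Fisher's exact test, adjusted p = 6.2e-48). Chromosome 20 held 99 Calu-3 peaks (6.56%) and 459 16HBE14o- peaks (14.1%, Fisher's exact test, adjusted p = 6.6e-14). The Calu-3 CEBPB list had 10.7% of its peaks on chromosome 3 and 2.40% on chromosome 20. For chromosome 20 the difference of -7.51 points was -4.86 in the 50% of each list with the higher signal.

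**Figure D3:**
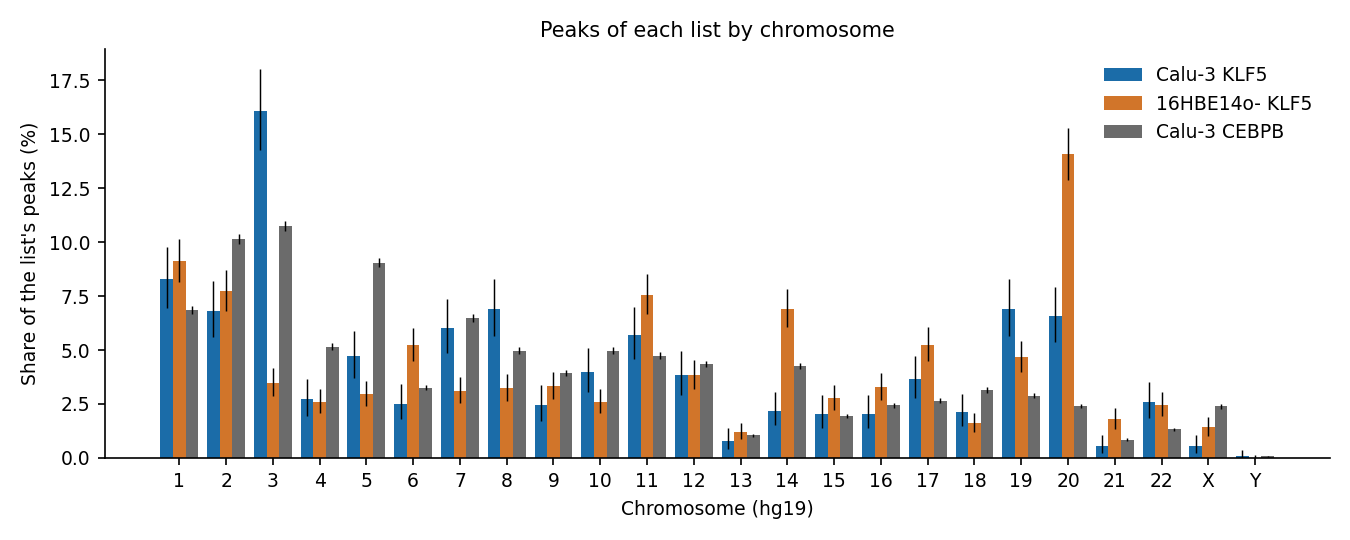
Percent of each list's peaks on each chromosome, with exact 95% confidence intervals as error bars. Chromosome 3 is highest for Calu-3 KLF5, at 16.1%, and chromosome 20 is highest for 16HBE14o- KLF5, at 14.1%.

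Along chromosome 3, 9.47 of the 12.6 points of Calu-3 excess came from beyond 150 Mb. That region held 155 Calu-3 KLF5 peaks (10.3%, 8.78 to 11.9), 26 16HBE14o- KLF5 peaks (0.797%, 0.521 to 1.17) and 2416 CEBPB peaks (3.48%). In the comparison of 603 bins of 5 Mb, 16 bins held a higher share of the Calu-3 list, and 9 of these were among the 10 bins of chromosome 3 beyond 150 Mb. The Calu-3 KLF5 peaks there had a median signal percentile of 29.1, and 51 of the 155 had a CEBPB peak (32.9%), against 44.9% elsewhere (Fisher's exact test, p = 0.00468). That test took no account of signal. In the whole Calu-3 list, the lowest 25% by signal had CEBPB at 35.5% of peaks (30.7 to 40.6), so the lower share may not be particular to the region. Of the 155 Calu-3 peaks 8 were shared, as were 8 of the 26 16HBE14o- peaks, and such counts are bounded by the shorter list in a region chosen for its unequal numbers. On the same chromosome between 85 and 90 Mb, 43 16HBE14o- KLF5 peaks (1.32%) stood against 1 Calu-3 peak. The difference in that bin, -1.25 points, was -0.726 in the 50% of each list with the higher signal, -0.728 with lists of 1510 peaks and -0.226 (Fisher's exact test, p = 0.654) among KLF5 peaks of the highest score. In all, 6 of the 603 bins held a higher share of the 16HBE14o- list, this bin among them, and 3 of the 6 were on chromosome 20. Beyond 25 Mb on that chromosome lay 444 16HBE14o- and 92 Calu-3 KLF5 peaks.

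**Figure D4:**
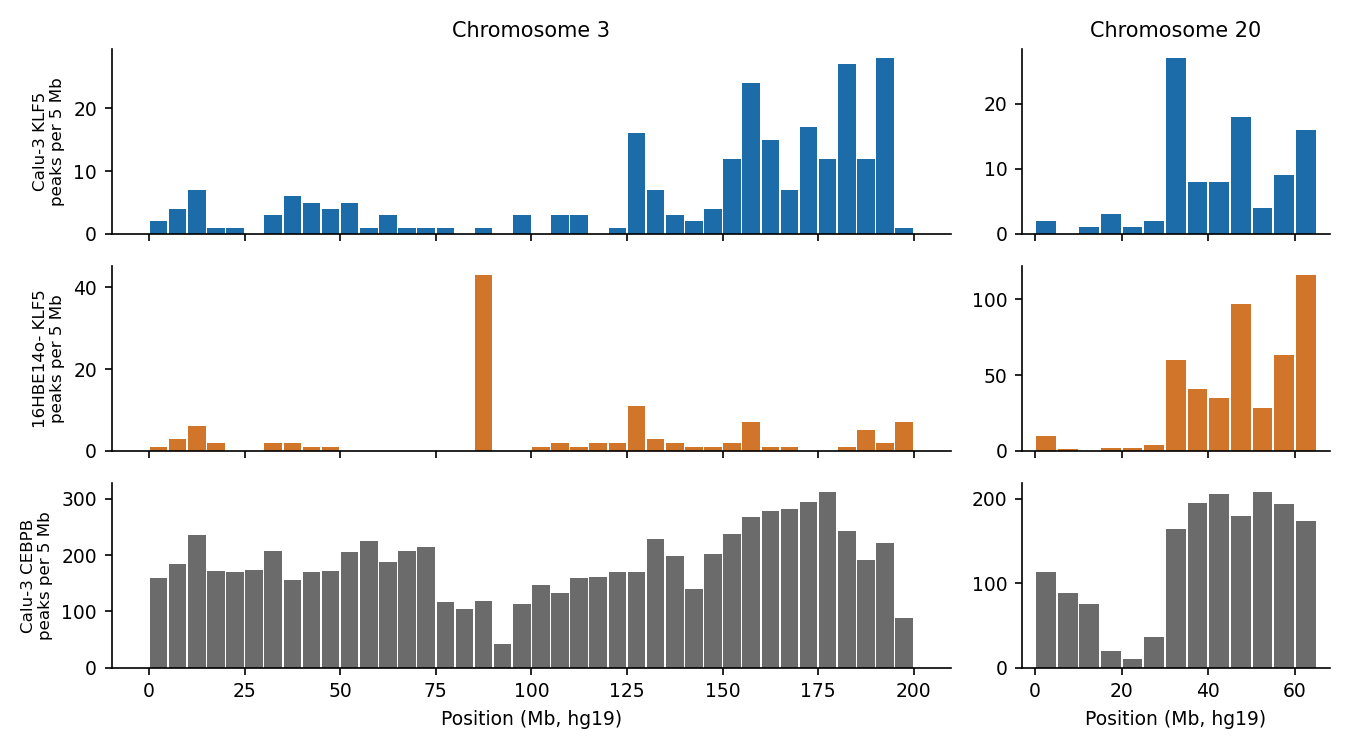
Number of peaks per 5 Mb bin along chromosomes 3 and 20, by position in Mb on hg19, with 1 row of panels per list and a separate vertical scale for each panel. Calu-3 KLF5 reached 28 peaks between 190 and 195 Mb of chromosome 3, where 16HBE14o- KLF5 had 2, and 16HBE14o- KLF5 reached 43 between 85 and 90 Mb and 116 between 60 and 65 Mb of chromosome 20.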

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

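The results in this part were picked out because the 2 KLF5 lists differed by a test of the difference itself. The comparisons of chromosomes, regions, bins and of the CEBPB peaks with the highest signal were chosen after the data had been seen, as were the tests by chromosome, with KLF5 lists of equal size, of the regions of chromosome 3 by CEBPB count and overlap, and of the relation across bins with and without the region.

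CEBPB overlapped Calu-3-only KLF5 peaks more often than KLF5 peaks found only in 16HBE14o-, by 24.6 points, and the CEBPB peaks concerned were in the top 10% by signal more often by 50.6 points. Stratified by chromosome, the odds ratio of the overlap was 3.28 (2.79 to 3.84), which argues against the placement of the peaks on different chromosomes as the whole cause. The difference was 22.3 points (18.7 to 25.9) with both KLF5 lists limited to the same number of peaks, and 25.5 points (22.3 to 28.6) with all peaks set to 200 bp, which argues against weaker peaks in the longer list and against peak width. The rabbit antibody used for 1 Calu-3 KLF5 sample cannot be told apart from the cell line, since 0 lists of a single sample were analysed here. A biological difference, with both factors at sites active in Calu-3, may account for the pattern but stays a hypothesis, because CEBPB was not measured in 16HBE14o- among the samples analysed here.

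Chromosome 3 held a share of the KLF5 peaks that was 12.6 points higher in Calu-3, and the part beyond 150 Mb accounted for 9.47 points. The excess was 6.42 points (4.70 to 8.50) in the 50% of each list with the higher signal, which argues against weak peaks as its whole cause. A candidate explanation is a gain of this region in the genome of Calu-3. Its 10 bins had a median percentile of 97.9 by CEBPB count among 603 bins, with a range of 38.3 to 99.8. Their median was 254.5 CEBPB peaks, against 117 over all bins. Outside the region, 53 bins lay above percentile 90 by CEBPB count. Of these, 29 had a higher KLF5 share in Calu-3 and 22 in 16HBE14o-, with 1 past the threshold each way. With medians of 1 Calu-3 and 2 16HBE14o- KLF5 peaks per bin, few bins could pass the threshold, so the number that did shows little. Bins with many CEBPB peaks leaned either way, and a high CEBPB count alone is weak evidence of a gain. The relation across bins did not decide on it. The log2 ratio of Calu-3 to 16HBE14o- KLF5 counts, with 0.5 added to each, rose with the CEBPB count over all 507 bins used (Spearman rho = 0.259, rotation test, p = 0.00197). It rose alike without the region (rho = 0.222, rotation test, p = 0.00201) and without chromosomes 3 and 20 (rho = 0.211, rotation test, p = 0.00219). A relation that holds outside the region does not single the region out, nor does it exclude a gain there. Binding of both factors at many sites of the region without any gain stays open and untested. The lower share of Calu-3 KLF5 peaks with CEBPB in the region, 32.9% against 44.9% elsewhere, does not decide between a gain and such binding. Either leaves open whether both factors sat at the same sites.

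On chromosome 3 between 85 and 90 Mb, the share of KLF5 peaks in Calu-3 minus that in 16HBE14o- was -1.25 points, and -0.226 points, not past the threshold, among KLF5 peaks of the highest score. An artifact of the reference sequence common to all libraries could place CEBPB peaks at the same positions. Only 3 of the 43 16HBE14o- KLF5 peaks had one (6.98%, 1.46 to 19.1), against 22.6% elsewhere. This argues against such an artifact as the whole cause only if the CEBPB list, whose filters were not given, kept artifact peaks. The margin was narrow with peaks less than 5 kb apart counted as 1 group, at 3 of 34 groups (8.82%, 1.86 to 23.7) against 24.7% elsewhere, and the test first used, the bin's percentile of 51.3 by CEBPB count, had decided neither way. The 43 peaks had a median signal percentile of 35.0, and a group of 5 entries at 87658551 to 87667137 had one of 12.4. An artifact behind part of the peaks, or one particular to the 16HBE14o- libraries, stays open and untested. A gain of this region in 16HBE14o- cannot be told apart from KLF5 binding particular to that line, because 0 lists of another factor in 16HBE14o- were analysed here.

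On chromosome 20 the share of KLF5 peaks in Calu-3 minus that in 16HBE14o- was -7.51 points. There 43 of the 99 Calu-3 KLF5 peaks were shared (43.4%, against 22.2% elsewhere). Of the 459 16HBE14o- KLF5 peaks, 46 were shared (10.0%, against 11.5% elsewhere). No explanation of the chromosome 20 difference was tested. Across the genome, 6 chromosomes and 16 bins of 5 Mb held a higher share of the Calu-3 KLF5 list, and 8 chromosomes and 6 bins held a higher share of the 16HBE14o- KLF5 list. These differences are not independent, because shares within a list have a fixed total.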

How the results depend on the processing

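Under 14 alternative settings, 17 results were recomputed 175 times. Of these, 163 kept their side of the threshold, 11 newly passed it, 1 no longer passed it and 0 passed it in the opposite direction. Some of the 163 could not change, so the tally overstates stability. The chromosome and region shares did not depend on the overlap rule, the peak width or the CEBPB filter. The KLF5 overlap between lines and the signal of its shared peaks did not involve CEBPB, so the filter on CEBPB q-values could not move them. The signal difference with and without CEBPB, which had not passed, changed sign to -1.92 points in the higher 50% by signal. The overlap of Calu-3 KLF5 peaks with 16HBE14o- KLF5 ranged from 18.1% to 25.3%, that with CEBPB from 17.4% to 45.6%, and the difference in CEBPB overlap between Calu-3-only peaks and those found only in 16HBE14o- from 17.6 to 28.8 points. Shared against Calu-3-only peaks, the difference in CEBPB overlap passed the threshold at -6.38 points with 50% of the shorter peak overlapped, -8.05 with summits within 100 bp, -10.5 in the higher 50% by signal, -10.1 with lists of 1510 peaks, -8.60 with CEBPB q-values of 0.05 or less and -8.22 without chromosomes 3 and 20. The signal difference between Calu-3 KLF5 peaks with and without CEBPB passed it at 7.35 points with 50% overlap, 8.01 with summits within 100 bp, 14.8 with lists of 1510 peaks, 6.26 with peaks of 200 bp and 5.33 when ranked by q-value. At 85 to 90 Mb of chromosome 3, the difference no longer passed it among KLF5 peaks of the highest score, at -0.226 points. In each case the cause was not tested. The filter on CEBPB q-values, the highest score, the exclusion of chromosomes, the local shifts and the stratified test were chosen after the data had been seen. The other settings had been planned, but not for every result. For the signal difference with and without CEBPB, the 50% overlap, the lists of 1510 peaks and the peaks of 200 bp were not planned. Alternatives used 1000 shifts or 10000 resamples, and the 50% overlap was set against the chance level of 1 bp. No paired analysis was possible because each list was made from both samples of its group, and leaving out a sample was not possible for the same reason. The alternatives planned for promoters, motifs and gene lists were not run. Depth is unknown and may limit which peaks each list holds: limiting all lists to 1510 peaks lowered the share of 16HBE14o- KLF5 peaks with CEBPB from 22.4% to 2.98%.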

Other observations

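Some peaks stood in groups of entries less than 5 kb apart. In the Calu-3 KLF5 list the group with the most entries held 10 entries on chromosome 8 at 145010724 to 145027210, with a median signal percentile of 81.7, followed by 6 entries on chromosome 3 at 193852227 to 193859526 with a median percentile of 96.6, which included the highest peak of the list. In the 16HBE14o- KLF5 list, 12 entries stood on chromosome 20 at 60925021 to 60945393 and 8 at 62165378 to 62177666. The first of these spans also held a group of 4 Calu-3 KLF5 entries, at 60932238 to 60937126. A group of 6 entries in the 16HBE14o- list, on chromosome 15 at 20545815 to 20550794, ranked low, with a median percentile of 7.85.

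The 3 largest groups of CEBPB peaks were of low signal. On chromosome 21, 29 entries at 10807083 to 10856214 had a median percentile of 13.5 and 18 entries at 10773536 to 10796595 had one of 19.2, and 17 entries on chromosome Y at 58975400 to 58997721 had one of 13.5. The next groups ranked higher, with 10 entries on chromosome 3 at 178440467 to 178454391 (median percentile 45.9) and 9 on chromosome 7 at 1260536 to 1281685 (57.1). These groups were looked for after the data had been seen, and no explanation of them was tested.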
